A study of Mus musculus with 24 samples.

How the data were processed

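RNA levels were measured by sequencing in 10 libraries of mouse cells, in 5 groups of 2: WT embryonic stem cells at day 0, and embryoid bodies at day 4 from WT cells and from the Smad2 knockout, Smad3 knockout and Smad2/3 double knockout. Groups and replicate numbers were taken from the labels. The series lists 24 samples, and the 14 of chromatin immunoprecipitation were not analysed here. The file names fall into 2 name series, used as the sequencing submission: the second holds replicate 2 of WT day 0, WT day 4, the Smad2 knockout and the Smad3 knockout. The labels give no such batch, and no separate cultures.

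The authors deposited 1 gene table per library. The expected counts, per the file headers, are RSEM's estimates of reads per gene, and 12.2 to 14.6% of genes had values that are not whole. The TPM and FPKM values were made by the authors with RSEM, per the file headers, and TPM sums to the same total in each library; FPKM was not used. The submitters' processing notes name FastQC 0.11.5, Bowtie2, STAR, RSEM, HOMER and the mm10 build, with no role or order, and the annotation version is not given in the sources used here. The tables hold 53379 genes, of which 20602 had no count in any library. Gene positions and symbols came from GENCODE M21 on the same build, matched by gene ID (50604 with the version, 53274 without, 105 unmatched); 79 symbols belong to more than 1 ID. Whether counting used strand is not given in the sources used here, so genes with antisense or overlapping partners, like those with near copies (the Rhox, Xlr, cathepsin and serpin families), are uncertain.

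Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr, 1 fit over all 5 groups with 5 residual degrees of freedom). The filter kept 19470 genes, the common biological coefficient of variation was 0.248 and the prior degrees of freedom 4.33. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM used TMM-scaled totals. A prior count of 2 entered the log2 CPM values, such as those of the list tests, and not the log2 fold changes, which came from the edgeR fit. The comparisons were WT day 4 against day 0, each knockout against WT, the 3 contrasts between knockouts, and the interaction (the effect of Smad2 loss in the Smad3 knockout minus that in WT). Each knockout was also tested for the sets of genes that WT cells induced or repressed more than 2-fold. Simulations of unchanged knockouts (10) gave values with no effect for shared calls and sets. All libraries were drawn anew in them, those of day 4 around the WT day 4 mean, gene by gene with the fitted dispersions. They therefore lack deviations that genes or libraries share.

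Before the data were examined, 27 gene lists were fixed: naive pluripotency, core pluripotency, primed epiblast, primitive streak, axial mesendoderm and organizer, definitive endoderm, mesoderm, cardiac, hematoendothelial, neuroectoderm, surface ectoderm, extraembryonic endoderm, trophoblast, primordial germ cell, fibroblast and stroma, Nodal and Activin response, SMAD pathway components, BMP, WNT and FGF response, epithelial-mesenchymal transition, hypoxia and glycolysis, p53 targets, G2/M cell cycle, cholesterol synthesis, imprinted and Y-linked genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1, correlation preset at 0.01), again with a correlation estimated per list, and with fry. Estimated correlations were used as a check on every call.

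The named genes followed a rule fixed before the data were examined: a panel of 20 genes with Smad2 and Smad3 first, up to 3 called members and 1 in the other direction from each list described, and the 5 largest rises and falls (3 each way between knockouts and for the interaction) among called genes of at least 5 CPM in the higher group whose libraries did not overlap. Some were left out for length. A later, shorter choice, made after the alternatives had been run, had dropped mainly genes whose sign turned under them; it was withdrawn, the earlier choice was restored, and the panel is given for the interaction. Results of some genes are not reported here.

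Depth was 35733249 to 53672980 expected counts per library. Floors (3 counts over a group) and 95% exact intervals for groups of 1 to 3 counts cover counting error only. The steps were tested on simulated counts for 19470 genes in the Smad2 knockout and WT libraries with 200 changed genes: 18% of 2-fold and 82% of 4-fold changes were called, with 0 wrong signs and 7 false calls. Libraries of a group correlated at 0.981 to 0.994 on log2 TPM and differed by more than sampling noise.

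Alternatives fixed beforehand were RLE size factors, library totals, no filter and a stricter filter, the replicate number or submission as a block, the compared groups alone, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1) (14328 genes with a mean TPM of at least 1), a fold threshold, and leaving out each library in turn, where a lone library is assumed to vary like the others. A length and GC offset (mgcv 1.9-3), leaving out chromosomes 18 and Y, list counts without single doubted libraries, pairing the WT day 4 and Smad3 knockout libraries by number (other groups unpaired), and splitting the WT day 4 libraries 1 and 1 for shared calls were added after seeing the data.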

Results

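RNA was sequenced from 10 samples of mouse cells. Undifferentiated E14 embryonic stem cells were sampled at day 0. Embryoid bodies, the aggregates that stem cells form and differentiate in once the self-renewal factor LIF is withdrawn, were sampled at day 4. The day 4 samples came from wild-type (WT) cells and from cells labelled as Smad2 knockout, Smad3 knockout and Smad2/3 double knockout. SMAD2 and SMAD3 carry Nodal, Activin and TGF-beta signals from the receptors to the nucleus, where FOXH1 is a known DNA-binding partner. Each of the 5 groups held 2 libraries, with 35733249 to 53672980 expected counts per library, and 19470 genes were tested. Levels below are means in CPM (library-scaled counts, TMM totals) with the SD over n = 2 libraries. The labels do not say that the libraries of a group came from separate cultures, and both libraries of a knockout carry 1 line number, so p-values measure the spread between these libraries and a knockout cannot be separated from its line. The file names fall into 2 series, taken below as 2 sequencing submissions. The labels give no such batch, and both double knockout libraries belonged to the first series. Chromatin immunoprecipitation samples of the series were not analysed here.

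The targeted genes were examined first. Smad2 (ENSMUSG00000024563.15, chromosome 18, 76241580 to 76310963, mm10) stood at 44.1 ± 8.2 CPM in WT at day 4, 38.8 ± 0.71 in the Smad3 knockout, 19.8 ± 0.8 in the Smad2 knockout and 22.4 ± 0.34 in the double knockout. The log2 fold change from WT was -1.16 (SE 0.18, adjusted p = 0.00245) in the Smad2 knockout and -0.98 (SE 0.18, adjusted p = 0.0047) in the double knockout. In the double knockout the 32 genes beyond Smad2 on chromosome 18 had a median log2 difference from WT of -1.16. The Smad2 value there is therefore not clear of a shift of that region. Smad3 (ENSMUSG00000032402.12, chromosome 9, 63646767 to 63757994) stood at 43.4 ± 2.0 CPM in WT, 30.9 ± 0.15 in the Smad2 knockout and 26.8 ± 1.6 in the double knockout (adjusted p = 0.0405 and 0.0136). In the libraries labelled Smad3 knockout it stood at 49.2 ± 0.68 CPM, a log2 difference of 0.18 (SE 0.16, adjusted p = 0.607). Smad3 RNA therefore did not check that label, since a gene-level count can include transcripts that carry a short edit, and the names Smad3 knockout and double knockout below are those of the labels. With a length and GC offset, chosen after the data were seen, the Smad2 value in the Smad2 knockout was -0.17 (adjusted p = 0.283). The Smad2 call in the double knockout was lost with the compared groups alone (adjusted p = 0.0562) and on the TPM scale, the Smad3 call there without either double knockout library (0.0736 and 0.12), and the Smad3 call in the Smad2 knockout without any 1 of the 10 libraries (0.0565 to 0.109). At day 0 Smad2 stood at 20.5 ± 2.0 and Smad3 at 9.38 ± 1.1 CPM.

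**Figure D1:**
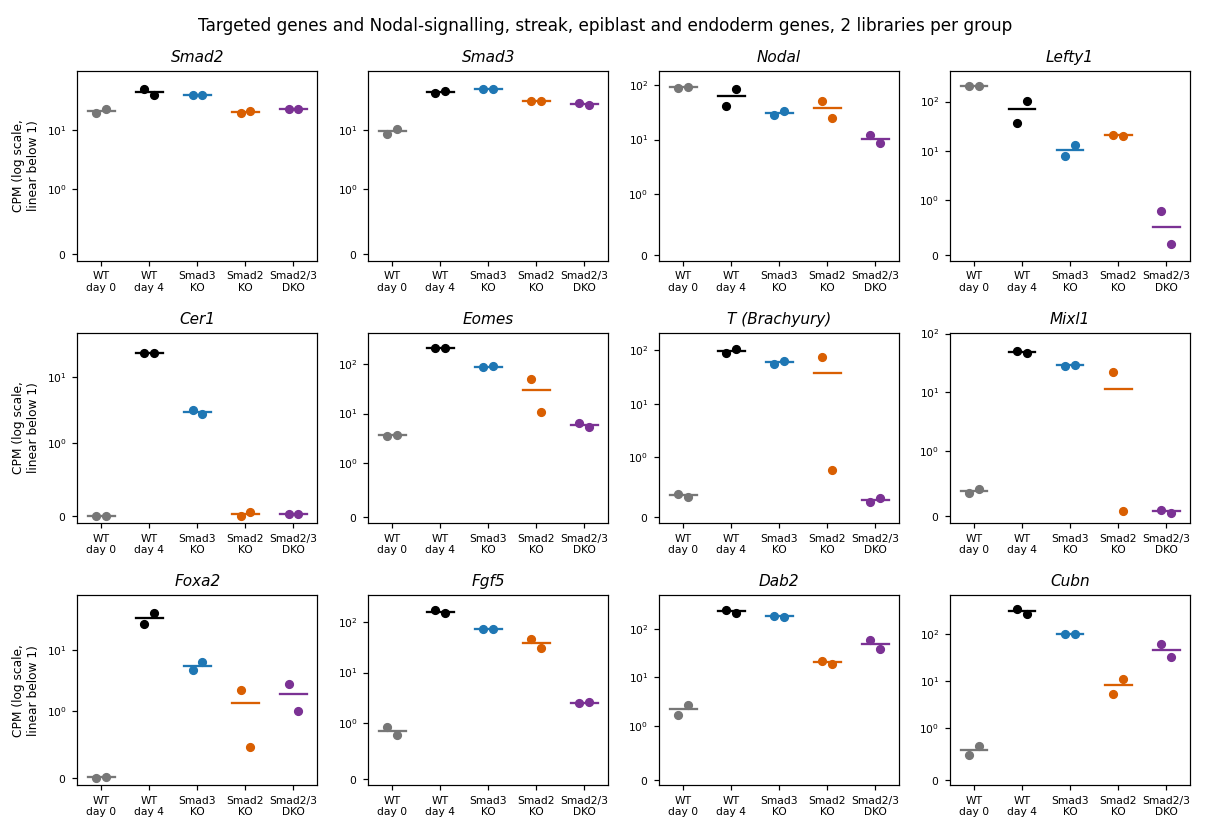
CPM of the targeted genes and of Nodal-signalling, streak, epiblast and endoderm genes in each library (points, 2 per group; bars, group means), on an axis that is logarithmic above 1 and linear below. Cer1 stands at 23.5 CPM in WT at day 4 and under 0.1 CPM in the Smad2 and double knockouts, and T differs between the Smad2 knockout libraries (74.3 and 0.79 CPM).

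The first comparison asked how WT cells change between the pluripotent state and day 4. Genes of naive pluripotency fell, and genes of the primed epiblast, primitive streak, organizer and both kinds of endoderm rose. All 20 naive pluripotency genes were called lower, with a median log2 fold change of -2.54. Klf4, a reprogramming factor, fell from 157 ± 28 to 8.53 ± 3.3 CPM, Nr0b1 from 105 ± 3.9 to 4.2 ± 1.5, and Tbx3 had a log2 fold change of -2.39 (adjusted p = 6.5e-05). Of the shared pluripotency factors, Pou5f1 had a log2 fold change of -1.72 (SE 0.3, adjusted p = 0.00152), Sox2 -1.44, Tdgf1 -1.11, Dppa2 -1.47 and Nanog -0.87 (adjusted p = 0.00235). Among the primed epiblast genes, 12 of 14 were called higher, led by Fgf5, a marker of the post-implantation epiblast, at 161 ± 13 CPM (log2 fold change 7.55, SE 0.28, adjusted p = 5.74e-06), with Sall2 at 4.78, the DNA methyltransferase gene Dnmt3b at 2.63 and Otx2 at 2.32.

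Mesendoderm genes went from near absence to clear expression in WT. Of 16 primitive streak genes 11 were called higher and 2 lower: T, the streak regulator Brachyury, rose from 0.365 ± 0.033 to 98.4 ± 11 CPM (adjusted p = 0.0038), Eomes to 217 ± 2.4 CPM (log2 fold change 5.91) and Mixl1 to 49.2 ± 3 CPM (6.96), while Mesp1, at 2.04 ± 1.2 CPM, was not called (adjusted p = 0.105). The organizer list had 10 of 12 called higher. Its gene Cer1, a secreted Nodal inhibitor, had no count at day 0 and 23.5 ± 0.16 CPM at day 4, at least 559-fold higher against a floor of 3 counts over the group. Lhx1 was at least 1020-fold higher by the same floor, and Gsc rose by 3.2 and Cyp26a1 by 7.47 on the log2 scale. In the definitive endoderm list 11 of 16 were called higher, among them Sox17 (5.74) and Foxa2, which had 1 count at day 0 and a ratio of 2400 (95% counting interval 431 to 95000). The extraembryonic endoderm list, the yolk sac lineage, had 19 of 22 called higher, with Dab2 at 226 ± 27 CPM, the endocytic receptor gene Cubn at 300.0 ± 48 and Gata6 at 16.4 ± 1.4 CPM, and Rhox5 called lower (-0.78, adjusted p = 0.0408). The secreted liver and yolk sac genes Ttr and Apoa4 were at least 389-fold and 334-fold higher, and Afp, with 1 count at day 0, had a ratio of 3040 (545 to 120000). The neuroectoderm list was not called by camera (adjusted p = 0.406; by fry it was higher, 0.024): 9 of its 20 genes were called higher and 4 lower, among these Sox1 (-1.59) and Pax6 (-1.07).

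Genes of the Nodal feedback loop did not share a direction in the edgeR test. The Nodal antagonist Lefty1 fell from 208 ± 3.3 to 69.9 ± 46 CPM (log2 fold change -1.57, adjusted p = 0.0242), Smad7 had -1.0 (adjusted p = 0.00501) and Skil, a SMAD co-repressor, 2.31, while Nodal (-0.5, adjusted p = 0.285) and Lefty2 (-0.59, adjusted p = 0.461) were not called. On the TPM + 1 scale Smad7 turned to 0.46 (not called) and Lefty1 (-0.95) lost its call, as it did with the length and GC offset (-0.55). The imprinted genes Igf2 and H19 rose by 3.01 and 2.63 on the log2 scale, with 14 of 23 imprinted genes called higher.

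In all, 10139 genes were called between WT day 4 and day 0, 5622 higher and 4517 lower. List tests (camera, preset correlation) gave adjusted p = 3.04e-08 for naive pluripotency, 0.000412 for primed epiblast and for definitive endoderm, 0.000261 for organizer, 1.1e-06 for extraembryonic endoderm, 0.0416 for primitive streak, 0.00138 for SMAD pathway components (14 of 20 higher), 0.00814 for imprinted genes and 0.0416 for primordial germ cell genes (6 of 10 lower). With an estimated correlation the lowest adjusted p was 0.367, so 0 of the 9 list calls held. Adjusted over the list alone, the member counts above were the same except for imprinted genes (15 higher) and SMAD pathway components (16 higher); in all that follows, where no such second count is given it equals the first. Log2 differences taken within each submission correlated at 0.84 across all genes. With the length and GC offset 7059 of the 10139 calls were kept, 808 changed sign and 164 of these were called in the opposite direction. The count was 6504 without WT day 0 replicate 1, and the primitive streak and germ cell calls were lost with the submission as a block (adjusted p = 0.0569 and 0.0572) and without WT day 4 replicate 2 (0.163 and 0.136). The streak call was lost also without WT day 0 replicate 2, the germ cell call also with the replicate block (0.0502) and the imprinted call with the length and GC offset (0.252), and log2(TPM + 1) values split the calls as 7098 higher and 1487 lower. Nanog, Sox2 and Tdgf1 lost their calls on the TPM scale, Rhox5 turned to 0.08 there and to 0.52 with the length and GC offset (not called), and Lefty1, Mixl1, Gsc, Sox1, Pax6 and Rhox5 lost theirs without 1 or another of the WT libraries.

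The next comparison asked what loss of Smad2 changes at day 4. Trophoblast and surface ectoderm genes were higher in the Smad2 knockout than in WT, and endoderm, organizer and primed epiblast genes were lower. Of 14 trophoblast genes 12 were called higher and 0 lower, with a median log2 fold change of 3.76: the X-linked homeobox genes Rhox9 (1.01 ± 0.23 to 55.5 ± 22 CPM, log2 fold change 5.78, SE 0.39, adjusted p = 0.00017), Rhox6 (5.64) and the placental homeobox gene Esx1 (3.74) had the smallest adjusted p of the list. Of 13 surface ectoderm genes 9 were called higher, including Dlx3 (3.2) and the keratins Krt8 (113 ± 64 to 1220 ± 370 CPM, log2 fold change 3.43) and Krt18 (2.44). They rose in the same libraries as the trophoblast genes, and whether surface ectoderm cells or trophoblast cells expressed them was not tested. Hand1 (5.34), Gata2 (4.02), Id2 (2.13) and Bmp4 (1.88) were also higher, and 7 of 16 BMP response genes were called higher and 0 lower. Rhox6 and Rhox9 are near copies of other Rhox genes, so the split of reads between them is uncertain.

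Endoderm and organizer genes were lower in the Smad2 knockout. In the extraembryonic endoderm list 15 of 22 were called lower and 1, Krt19 (3.44), higher: Dab2 fell from 226 ± 27 to 20.3 ± 2.2 CPM (log2 fold change -3.48, SE 0.27, adjusted p = 0.000245), Cubn by 5.2, Gata6 by 3.32, Gata4 by 3.05 and Lama1 by 2.4 on the log2 scale. The apolipoprotein gene Apob had a log2 fold change of -6.81 (adjusted p = 9.49e-05). In the definitive endoderm list 13 of 16 were called lower, with Foxa2 at -4.68 (SE 0.71, adjusted p = 0.00219) and Sox17 at -2.49. Cer1 was left with 2 counts over both libraries against 2015 in WT, a ratio of 994 (95% counting interval 275 to 8210; adjusted p = 0.000132), and Lhx1 had -5.73, so that 8 of 12 organizer genes were called lower. Of 14 primed epiblast genes 10 were called lower, among them Dnmt3b (-2.13), Fgf5 (-2.08), Otx2 (-1.69) and Sall2 (-1.51), and Tdgf1 had -1.05 (adjusted p = 0.00409). Of 20 naive genes 10 were called higher, among them Dppa3 (2.96), Fbxo15 (1.35) and Socs3 (1.92), whereas Pou5f1 (0.36, adjusted p = 0.364) and Nanog (-0.36, adjusted p = 0.12) were not called. With the length and GC offset Pou5f1 was called lower instead (-0.7, adjusted p = 0.00459).

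Streak and Nodal feedback genes gave a less uniform picture in the Smad2 knockout. Eomes fell by 2.85 on the log2 scale (SE 0.54, adjusted p = 0.0047), Lefty1 by 1.77 (adjusted p = 0.0235), Skil by 1.83, Smad4 by 0.81 (adjusted p = 0.00659) and Gsc by 2.61 (adjusted p = 0.0223). T (log2 difference -1.39, adjusted p = 0.379), Mixl1 (-2.12, adjusted p = 0.208), Mesp1 (0.63, adjusted p = 0.693), Nodal (-0.75, adjusted p = 0.149) and Lefty2 (-1.83, adjusted p = 0.0566, or 0.0453 with the submission as a block) were not called. T stood at 74.3 CPM in replicate 1 and 0.79 in replicate 2, and 15 of the 16 streak genes were more than 2-fold higher in replicate 1. Without replicate 1, T (-6.96, adjusted p = 0.000209) and Mixl1 (-9.12) were called and 12 streak genes were called lower in place of 5, while Mesp1 turned to -4.53 (adjusted p = 0.0161) and the Lefty1 call was lost (adjusted p = 0.103). Lefty1 and Gsc also lost their calls without WT day 4 replicate 2 or Smad2 knockout replicate 2. Sox1 rose by 2.25 to 1.96 ± 0.72 CPM.

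Single imprinted genes and the Y-linked genes also differed between the Smad2 knockout and WT, while the imprinted list was not called by camera. H19, an imprinted noncoding RNA, had a log2 fold change of 4.58, Igf2, a fetal growth factor gene, 3.97 (adjusted p = 9.49e-05), and Grb10, a growth inhibitor, fell by 4.89. All 5 Y-linked genes tested were called lower. Uty had no count in the Smad2 knockout and was at least 664-fold higher in WT, Eif2s3y had 3 counts (ratio of WT 1790, 95% counting interval 612 to 8680), and Ddx3y had a log2 fold change of -8.93. Such near absence may be a trait of the line, so it is not read as an effect of Smad2 loss.

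In all, 6904 genes were called between the Smad2 knockout and WT, 2993 higher and 3911 lower, and log2 differences within each submission correlated at 0.67 across all genes. Camera gave adjusted p = 3.49e-08 for trophoblast, 1.22e-05 for surface ectoderm, 1.55e-05 for extraembryonic endoderm, 3.28e-05 for definitive endoderm and primed epiblast, 0.00114 for organizer, 0.000642 for BMP response, 0.00445 for naive pluripotency, 0.00185 for fibroblast and stroma genes (7 of 11 higher), 0.000718 for SMAD pathway components (13 of 20 lower), 0.00793 for FGF response (6 of 13 lower), 0.0137 for hypoxia and glycolysis (7 of 17 higher) and 0.000346 for Y-linked genes. With an estimated correlation the lowest adjusted p was 0.189, so 0 of these 13 calls held. Adjusted over the list alone, 10 surface ectoderm, 9 BMP response and 7 hypoxia genes were higher and 16 extraembryonic endoderm, 11 primed epiblast and 8 FGF response genes lower. Ribosomal protein genes took 13.2 and 12.37% of counts in the Smad2 knockout libraries, 15.3 and 11.28% at day 0 and 5.66 to 7.75% in the other libraries, and log2 fold changes from WT fell with transcript length (Spearman -0.63 across 11212 genes, which are not independent). With the length and GC offset 6155 genes were called, but only 3953 of the 6904 calls were kept in direction, 584 changed sign and 28 of these were called in the opposite direction. Only 2461 genes were called with the compared groups alone and 4571 without Smad2 knockout replicate 1, the naive call was lost without replicate 2 (adjusted p = 0.0652), and the split was 800 higher and 6168 lower on log2(TPM + 1).

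**Figure D2:**
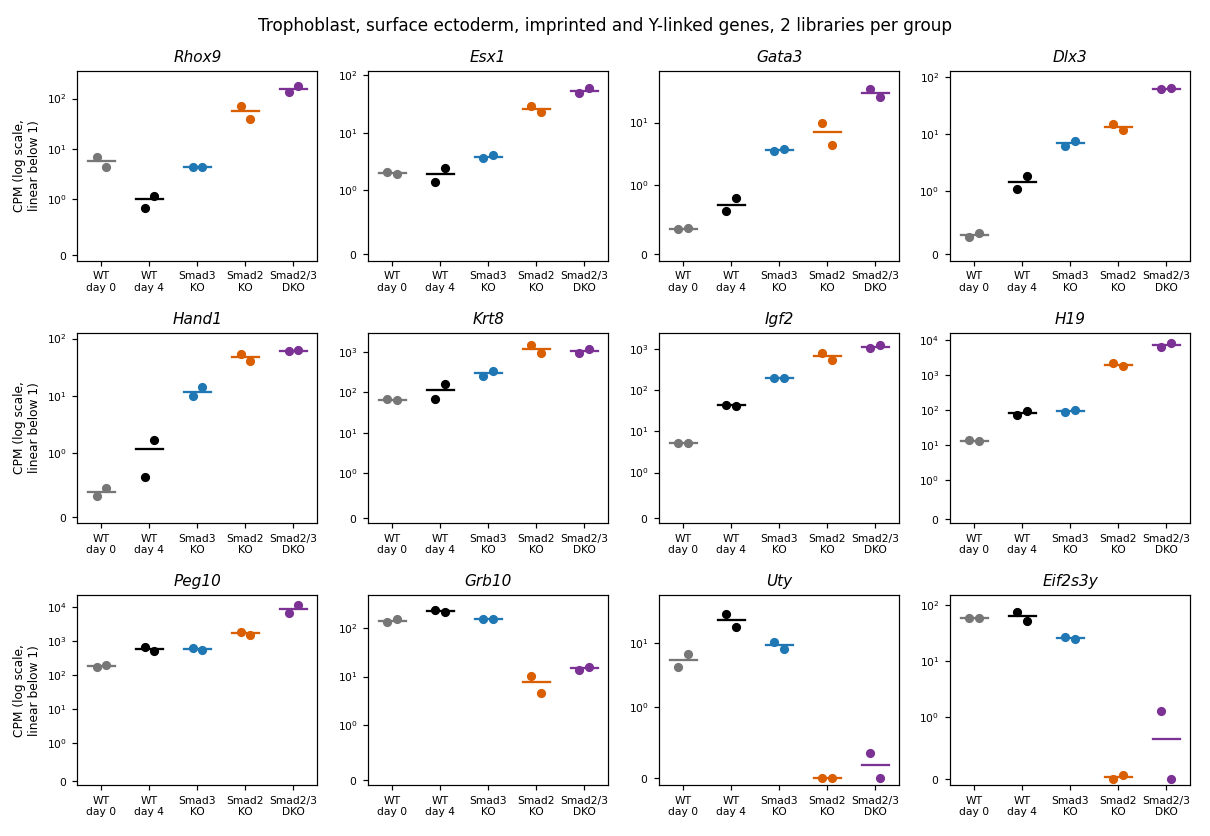
CPM of trophoblast, surface ectoderm, imprinted and Y-linked genes in each library (points, 2 per group; bars, group means), on an axis that is logarithmic above 1 and linear below. Rhox9 goes from 1.01 CPM in WT at day 4 to 55.5 in the Smad2 knockout and 155 in the double knockout, and Grb10 is low in the same knockouts.

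Loss of Smad3, under the label's name, was compared with WT in the same way. Few genes passed the test, and they included regulators of trophoblast and surface ectoderm that were higher and epiblast genes that were lower. Hand1 stood at 11.9 ± 3 CPM against 1.15 ± 0.76 in WT (log2 fold change 3.36, SE 0.41, adjusted p = 0.0174), and Gata3 (2.34), Dlx3 (2.22), Rhox9 (2.1, adjusted p = 0.0443) and Rhox6 (2.0, adjusted p = 0.0489) were higher. The vasodilator peptide gene Adm rose by 3.28 (SE 0.3, adjusted p = 0.00735), Rasgrf1 by 3.6, the complement gene C3 by 2.46, Igf2 by 2.2, Vegfa by 1.37 and Ndrg1 by 1.27. Cer1 fell from 23.5 ± 0.16 to 2.94 ± 0.28 CPM (-3.0, adjusted p = 0.0174), Fgf15 by 2.39 (adjusted p = 0.00779), Trh by 1.77, Lama1 by 1.23, Ccnd1 by 1.18, Dnmt3b by 1.15 and Nanog by 1.13 (adjusted p = 0.0321).

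The streak and Nodal feedback genes named here did not pass the unpaired test in the Smad3 knockout. As lists, Nodal and Activin response genes (median -0.78, camera adjusted p = 0.000793, by fry 0.0552) and organizer genes (-0.5, 0.0126, by fry 0.159) were called lower by camera, the organizer list not without WT day 4 replicate 2 (0.309). In each 1 gene was called lower, and adjusted over the list alone 5 and 3 (with 1 response gene higher). Camera with an estimated correlation gave adjusted p = 0.267 for the response list and 0.279 for the organizer list. Streak genes were not called as a list (-0.47, 0.106). The log2 differences were -1.26 for Eomes (adjusted p = 0.249), -0.7 for T (0.81), -0.77 for Mixl1 (0.792), -1.81 for Gsc (0.236), -2.62 for Foxa2 (0.102), -1.24 for Sox17 (0.226), -1.05 for Nodal (0.212) and -1.77 for Lefty2 (0.221). Lefty1 stood at 10.5 ± 3.6 CPM against 69.9 ± 46 (-2.74, adjusted p = 0.0569, or 0.0316 with the submission as a block). With WT and Smad3 knockout libraries paired by number, an alternative chosen after the data were seen, Lefty1 (-2.61, adjusted p = 0.00717) and Foxa2 (-2.61, 0.0496) were called, Eomes (0.176) and T (0.755) were not, and 512 genes were called in all. Smad2 (-0.19) and Smad4 (0.01) were not called.

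In all, 108 genes were called in the Smad3 knockout, 84 higher and 24 lower, log2 differences within each submission correlated at 0.51 across all genes, and 3343 had an unadjusted p under 0.05. Camera called 18 lists, among them primed epiblast (median log2 fold change -0.81, adjusted p = 6.46e-07), trophoblast (1.07, 1.58e-05), surface ectoderm (1.03, 0.000117), FGF response (-0.87, 2.11e-05), definitive endoderm (-0.72, 0.000363), mesoderm (0.96, 0.000363), core pluripotency (-0.55, 0.000363), cardiac (1.1, 0.000886), hypoxia and glycolysis (0.27, 0.000464), cholesterol synthesis (-0.33, 0.000231) and G2/M cell cycle genes (-0.35, 0.000793). With an estimated correlation the lowest adjusted p was 0.107, so 0 of the 18 held. By fry 11 did (not mesoderm, 0.16), and 13 were kept without each library in turn (cardiac had 0.0827 without WT day 4 replicate 2). Over all genes 3 trophoblast genes were called higher and 2 primed epiblast genes lower, and adjusted over the list alone 8 and 8. The count of calls rests on single libraries: it was 3 or 4 without Smad3 knockout replicate 1 or 2, 10 without either double knockout library, 25 without either day 0 library, 37 without WT day 4 replicate 1, 208 without either Smad2 knockout library and 2709 without WT day 4 replicate 2. Every gene named above as called, apart from Adm, lost its call without either Smad3 knockout library, and with only the 2 groups in the edgeR fit 0 genes were called, where 2421 had an unadjusted p under 0.05 (over all groups DESeq2 called 791, a length and GC offset 1505, the submission block 278).

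**Figure D3:**
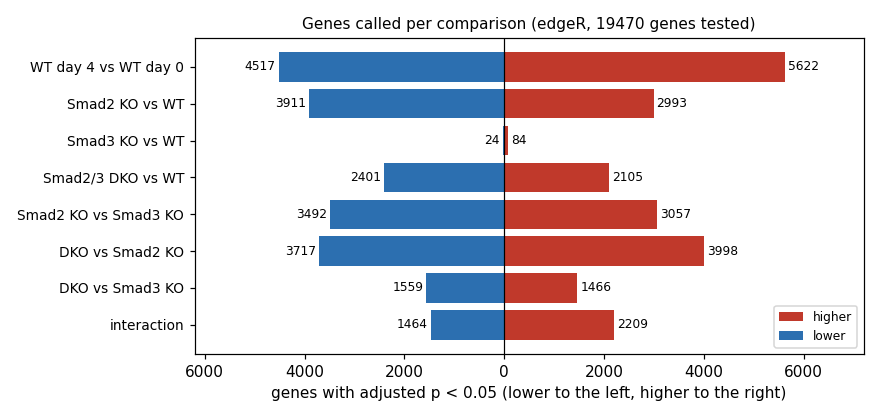
Genes called higher and lower in each comparison (bars from 0; edgeR, adjusted p under 0.05, of 19470 tested). Against WT, 108 genes are called in the Smad3 knockout, 4506 in the double knockout and 6904 in the Smad2 knockout. These are counts of calls and not sizes of effect. The Smad3 knockout count was 0 with the compared groups alone and 1505 with the length and GC offset.

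The double knockout was compared with WT to ask what loss of both genes changes. Streak, organizer, epiblast and Nodal feedback genes were lower than in WT, most of them by large factors, and trophoblast, surface ectoderm and imprinted genes were higher. Of 16 primitive streak genes 14 were called lower (median log2 fold change -5.15): T stood at 0.287 ± 0.053 CPM against 98.4 ± 11 (-8.41, SE 1.71, adjusted p = 0.00735), Mixl1 at 0.0751 ± 0.041 against 49.2 ± 3 and Eomes at 5.84 ± 0.78 against 217 ± 2.4 (-5.21, adjusted p = 0.000449). Cer1 had 2 counts (ratio of WT 1070, 95% counting interval 296 to 8860; adjusted p = 2.83e-05) and Mesp1 1 count (ratio 185, interval 32.8 to 7350; adjusted p = 0.0316). The feedback genes Lefty1 (-7.07, SE 0.67, adjusted p = 0.000156), Lefty2 (-6.22) and Nodal (-2.64, adjusted p = 0.00177) were lower, and 13 of 19 Nodal and Activin response genes were called lower. Lefty2 had 107 and 5 counts in the double knockout libraries, and -9.55 and -5.32 without the first and the second. Lhx1 (-8.01), Gsc (-5.79), Foxa2 (-4.17) and Skil (-1.68) were lower too, while Sox17 (-1.27, adjusted p = 0.0812) and Smad4 (0.39, adjusted p = 0.126) were not called.

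All 14 primed epiblast genes were called lower in the double knockout. Fgf5 fell by 5.97 on the log2 scale (SE 0.25, adjusted p = 7.76e-06), Sall2 by 3.25 and Otx2 by 1.89. Of 13 FGF response genes 10 were called lower, among them Il17rd (-3.59), Dusp6 (-2.61), a phosphatase induced by FGF signalling, and Fgf15 (-4.8). Of 10 core pluripotency genes 6 were called lower, among them Tdgf1 (-1.82) and L1td1 (-1.57), with Pou5f1 at -2.09 (adjusted p = 0.00145) and Nanog at -0.82 (adjusted p = 0.00721), and Trh had -4.4. In the naive list Klf4 was higher (1.97), as were 7 of 20 genes in all, with 1 lower.

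Of 14 trophoblast genes 13 were called higher in the double knockout and 0 lower, with a median log2 fold change of 5.06. Rhox9 reached 155 ± 33 CPM (7.26, SE 0.41, adjusted p = 1.76e-05), Rhox6 225 ± 49 and Esx1 53.8 ± 7.7 CPM. Ctsj and Serpinb9g, members of placental gene families with near copies, had no count in WT and were at least 226-fold and 503-fold higher. Of 13 surface ectoderm genes 12 were higher, with Dlx3 at 5.41, Gata3 at 5.39 and Tfap2c at 2.73, and Hand1 rose by 5.74. Here too the surface ectoderm list was not told apart from trophoblast cells. Among 23 imprinted genes 13 were higher and 4 lower: H19 rose to 7340 ± 1100 CPM (6.46), Igf2 by 4.72 and the placental gene Peg10 by 3.94, while Grb10 fell by 3.91. All 5 Y-linked genes were called lower, with Uty at -6.99 and Eif2s3y at -6.6. In replicates 1 and 2 Eif2s3y had 61 and 0 counts, Uty 17 and 0 and Ddx3y 46 and 0. Whether replicate 1 held some cells of another line was not tested. The low Y-linked levels may be a trait of the line here too.

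In all, 4506 genes were called in the double knockout, 2105 higher and 2401 lower, and with no double knockout library in the second submission no within-submission value could be had for it there. Camera gave adjusted p = 2.71e-13 for trophoblast, 5.8e-12 for primed epiblast, 8.36e-09 for surface ectoderm, 2.75e-07 for FGF response, 5.34e-07 for primitive streak, 3e-06 for organizer (9 of 12 lower), definitive endoderm (11 of 16 lower) and Nodal and Activin response, 0.000614 for core pluripotency, 0.0113 for naive pluripotency, 0.00147 for BMP response (6 of 16 higher), 0.0231 for hypoxia and glycolysis (7 of 17 higher), 0.00179 for WNT response (8 of 15 lower), 0.0142 for imprinted genes and 0.000119 for Y-linked genes. With an estimated correlation the lowest adjusted p was 0.102, so 0 of the 15 list calls held. Adjusted over the list alone 13 definitive endoderm, 14 Nodal and Activin response, 11 FGF response, 10 organizer and 9 WNT response genes were lower, and 9 naive and 7 BMP response genes were higher. Lists not called included mesoderm (4 higher and 6 lower of 22, adjusted p = 0.659), hematoendothelial (0.951), neuroectoderm (0.33), primordial germ cell (0.519), epithelial-mesenchymal transition (0.204), p53 targets (0.0856) and extraembryonic endoderm (3 higher and 9 lower of 22, 0.252). The count was 2126 or 2166 without double knockout replicate 1 or 2, which also ended the calls of T and Mixl1, and 2778 with the compared groups alone; the streak count fell to 6 without replicate 1, and Mesp1 lost its call without either day 0 library, WT day 4 replicate 2 or either double knockout library. The naive list lost its call without double knockout replicate 1 (adjusted p = 0.0673), and the hypoxia list lost its call without WT day 4 replicate 1 (0.104) or double knockout replicate 2.

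**Figure D4:**
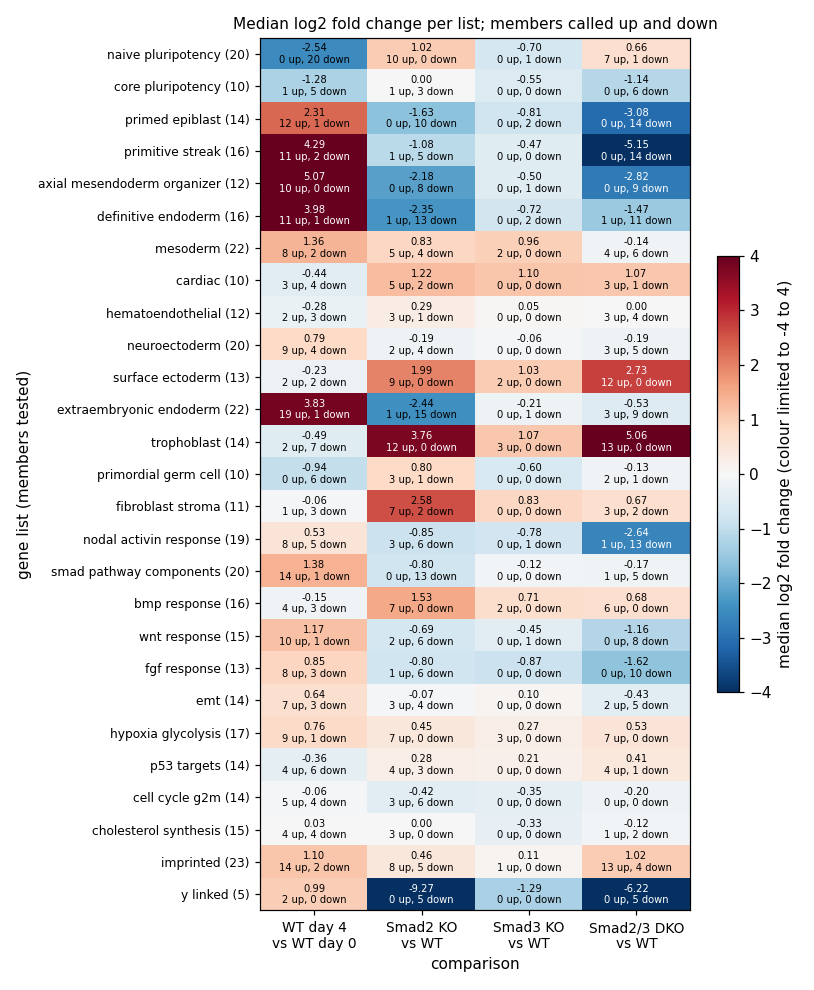
Heat map of the median log2 fold change of each fixed gene list (vertical axis) in 4 comparisons (horizontal axis), with the median and the members called up and down printed in each cell and colours limited to -4 to 4. Trophoblast genes have medians of 3.76 in the Smad2 knockout, 1.07 in the Smad3 knockout and 5.06 in the double knockout against WT.

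The single knockouts were compared with each other, a difference in which the WT libraries enter only through the common normalization, filter and dispersion. Trophoblast genes were higher in the Smad2 than in the Smad3 knockout (9 of 14 called higher, 11 adjusted over the list alone, camera adjusted p = 2.1e-05, 0.296 with an estimated correlation), and extraembryonic endoderm genes were lower (13 of 22, 14 over the list alone, 4.18e-05, also 0.296). Cer1 was lower by -6.8 on the log2 scale (SE 0.54, adjusted p = 0.000869), Eomes by -1.59 (0.0409) and Foxa2 by -2.06 (0.0386), whereas H19 (4.39) and Dppa3 (4.14) were higher. T (-0.7, adjusted p = 0.67), Mixl1 (-1.35, 0.417), Nodal (0.3, 0.565), Lefty1 (0.97, 0.157), Lefty2 (-0.06, 0.952) and Sox17 (-1.25, 0.0729) were not called. For T the value joins unlike libraries: it was -6.26 (adjusted p = 0.00039) without Smad2 knockout replicate 1 and 0.29 (0.316) without replicate 2. Smad2 differed by -0.97 (adjusted p = 0.00513) and Smad3 by -0.67 (0.0133). The test called 6549 genes, 3057 higher and 3492 lower, and log2 differences within each submission correlated at 0.73 across all genes. With the length and GC offset 4098 of these calls were kept and 267 changed sign. The count was 1898 and 2651 without Smad3 knockout replicate 1 and 2 and 8569 without WT day 4 replicate 1, the Eomes and Foxa2 calls were lost without either Smad3 knockout library or either day 0 library, Eomes also without either double knockout library and Foxa2 without Smad2 knockout replicate 2, Smad2 moved to -0.08 with the length and GC offset, and library totals gave 1571 higher and 5369 lower.

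The double knockout was then set against each single knockout, asking what the second loss adds. Against the Smad2 knockout, feedback genes were lower and yolk sac genes higher, and streak genes were lower by an amount that rests largely on Smad2 knockout replicate 1. Lefty1 differed by -5.3 (SE 0.63, adjusted p = 0.000659), Lefty2 by -4.39, Nodal by -1.89 (0.00577), Eomes by -2.36 (0.00858), T by -7.02 (0.00971), Mixl1 by -7.15 (0.016) and Pou5f1 by -2.45, and 13 of 16 streak genes were called lower (camera adjusted p = 0.00102, 0.743 with an estimated correlation). Cer1 was at a few counts in both (-0.09, adjusted p = 0.957), and Smad2 (0.18), Smad3 (-0.2) and Nanog (-0.46, adjusted p = 0.0507, or 0.0337 with the submission block) were not called. In the extraembryonic endoderm list 16 of 22 were higher (0.000128, estimated 0.39). Pappa2 (8.35), a placental protease gene, and Smad4 (1.19, adjusted p = 0.00117) were higher. Pappa2 had only 3 and 0 counts in the Smad2 knockout libraries. The immunoproteasome gene Psmb8 was lower (-6.97, adjusted p = 8.37e-05). The test called 7715 genes, 3998 higher and 3717 lower, of which 5296 were kept and 320 changed sign with the length and GC offset. Without either double knockout library 3733 and 3693 were called and T, Mixl1 and Eomes lost their calls. Without Smad2 knockout replicate 1 T stood at -1.46 (adjusted p = 0.013), Eomes at -0.9 (0.0138) and Mixl1 at -0.16 (0.907), with 6 of 16 streak genes called lower (camera adjusted p = 0.0248). Only 3 of 16 were called lower without double knockout replicate 1, Nodal lost its call without double knockout replicate 2 (adjusted p = 0.0576), and with the length and GC offset Smad2 turned to -0.69 (adjusted p = 0.00188).

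Against the Smad3 knockout, the double knockout had less of the streak, organizer and feedback transcripts and more of the trophoblast ones. Cer1 differed by -6.88 (SE 0.54, adjusted p = 0.000231), Lhx1 by -7.52, Eomes by -3.95 (0.00217), T by -7.72 (0.0144), Mixl1 by -8.5 (0.0168), Lefty1 by -4.33, Lefty2 by -4.45, Nodal by -1.59 (0.0239) and Pou5f1 by -1.61. Of 16 streak genes 14 were lower (camera adjusted p = 9.26e-07, 0.314 with an estimated correlation) and of 14 trophoblast genes 13 were higher (2.51e-13, 0.156), with Ctsj at 9.08. Ctsj had 1 and 0 counts in the Smad3 knockout libraries and 280 and 430 in the double knockout, so the size of its fold change is uncertain. Smad2 was lower by -0.79 (0.0179) and Smad3 by -0.87 (0.00677), and Foxa2 (-1.55, 0.142) and Smad4 (0.38, 0.165) were not called. The test called 3025 genes, 1466 higher and 1559 lower. Counts were 1149 and 1086 without Smad3 knockout replicate 1 and 2 and 1235 and 1028 without double knockout replicate 1 and 2; T and Mixl1 lost their calls without either double knockout library, Nodal, Smad2 and Smad3 without any 1 of these 4 libraries, and Pou5f1 without replicate 2 of either group.

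Chromosome 18, which carries Smad2, Smad4, Smad7, Gata6, Ttr and Fbxo15, stood apart in the double knockout. Among its genes with a mean of at least 5 CPM, the 233 that start before Smad2 had a median log2 difference from the Smad3 knockout of 0.54, with 192 above 0, and the 32 beyond Smad2 a median of -0.89, with 29 below 0. Against WT the medians were 0.35 and -1.16. In the Smad2 knockout against WT they were -0.27 and -0.36, and in the Smad3 knockout -0.2 and -0.27. Smad2 itself stood at -0.79 in the double against the Smad3 knockout and at -0.98 against WT. Its fall in the double knockout is therefore not clear of the shift beyond it. Leaving out the genes of chromosomes 18 and Y, an alternative chosen after the data were seen, left 4349 calls in the double knockout against WT.

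**Figure D5:**
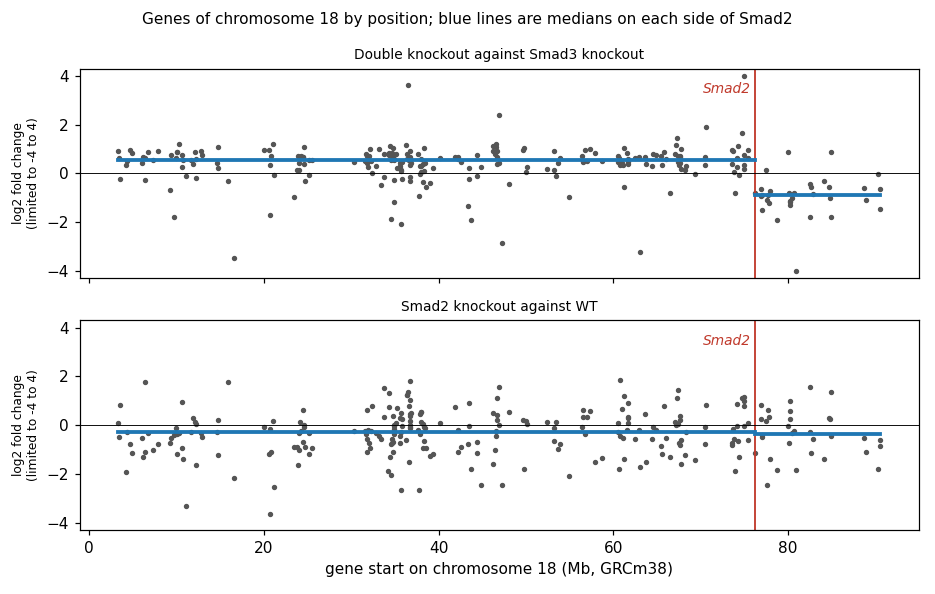
Log2 fold change of each chromosome 18 gene with a mean of at least 5 CPM (points, limited to -4 to 4) by gene start, for the double against the Smad3 knockout and the Smad2 knockout against WT, with medians on each side of Smad2 as lines. The medians are 0.54 and -0.89 in the first and -0.27 and -0.36 in the second.

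The interaction of both losses asked whether losing Smad2 has a different effect in WT cells and in cells labelled Smad3 knockout. It was called for 3673 genes, 2209 with a positive and 1464 with a negative value. Its values followed transcript length (Spearman 0.6). With the length and GC offset 2221 of these calls were kept and 87 changed sign. Among the panel genes called, Mesp1 (-9.61, adjusted p = 0.0255), Lefty1 (-2.56, 0.0475) and Pou5f1 (-1.96, 0.0166) had negative values, and Foxa2 (3.13, 0.0419), Sox17 (2.46, 0.0351) and Smad4 (1.19, 0.0128) positive ones. Smad4 lies on chromosome 18, where the median was 0.68. Pappa2 had 6.96 (adjusted p = 0.0059). T (-6.33, adjusted p = 0.0517, or 0.0452 with the submission block), Mixl1 (-6.38, 0.0761), Cer1 (2.91, 0.159), Lefty2 (-2.62, 0.0851), Eomes (-1.1), Nodal (-0.84), Gsc (-1.37), Foxh1 (-0.72), Sox1 (-1.27), Pax6 (0.41), Smad2 (0.36), Smad3 (-0.38) and Nanog (0.67) were not called. Counts without single libraries ran from 397 (Smad3 knockout replicate 2) to 7003 (WT day 4 replicate 2), with 1226 without Smad3 knockout replicate 1, 2006 without Smad2 knockout replicate 1 and 870 and 786 without double knockout replicate 1 and 2. Each of these panel calls was lost without 1 or more of the Smad3 or double knockout libraries; without Smad2 knockout replicate 1 Mesp1 stood at -4.45 (adjusted p = 0.11), Mixl1 at 0.62 and Eomes at 0.36. With no double knockout library in the second submission, no within-submission value could be had there.

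Genes that WT cells switched on or off were then followed as sets, to ask how far each knockout reached the WT program. The 4293 genes induced more than 2-fold in WT were lower in the Smad2 than in the Smad3 knockout, by a median log2 difference of -0.99 (camera adjusted p = 3.14e-47, 0.00854 with an estimated correlation), and the 3419 repressed genes were higher, by 0.95 (6.33e-33, 0.035 with an estimated correlation). Against the Smad2 knockout the double knockout stood at 0.76 for induced and -0.82 for repressed genes, and against the Smad3 knockout at -0.17 and 0.07. With an estimated correlation these had camera adjusted p = 0.0881, 0.123, 0.415 and 0.529. The values depended on the cut. Sets chosen at a log2 threshold of 2 gave 0.86 and -0.68 against the Smad2 knockout. Against the Smad3 knockout they gave -0.52 and 0.34 (camera, preset correlation, adjusted p = 2.47e-11 and 6.08e-06). Against WT day 4 they gave -0.55 and 0.69 in the double and -0.12 and 0.29 in the Smad3 knockout, with no simulation at that threshold. With the length and GC offset the sets were chosen anew (3769 induced and 2167 repressed genes). The values were then 0.49 and -0.27 against the Smad2 knockout and -0.34 and 0.28 against the Smad3 knockout. Against WT day 4 the induced medians were -1.11, -0.12 and -0.26 in the Smad2, Smad3 and double knockouts, and the repressed medians 1.04, 0.09 and 0.19. Single WT libraries moved these medians, with the sets chosen anew in each fit. Without WT day 4 replicate 2 the induced medians were -1.27, -0.32 and -0.47 and the repressed ones 1.45, 0.66 and 0.74. Without replicate 1 they were -0.98, -0.02 and -0.17 and 0.97, -0.02 and 0.16. Since the sets were chosen on the same WT libraries, unchanged knockouts were simulated 10 times, which gave -0.06 and 0.07. Each gene was drawn independently, so these values lack deviations shared across genes, such as those of single WT libraries above. Without WT day 4 replicate 2 the repressed set no longer differed between the double and Smad3 knockouts (0.01, adjusted p = 0.0864).

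The overlap of knockout effects was counted against the shared WT libraries. The Smad2 and double knockouts shared 830 genes called higher and 1183 called lower, where independent lists would share 323.6 and 482.3, and 263 genes were called in opposite directions. The Smad2 and Smad3 knockouts shared 55 higher and 19 lower (12.9 and 4.8 for independent lists, 6 opposite), and the Smad3 and double knockouts 63 and 18 (9.1 and 3, 0 opposite). Simulated unchanged knockouts shared 0 calls, which leaves out real effects and so gives no chance value for knockouts that have calls. Fold changes correlated across genes at 0.44, 0.35 and 0.51 in that order, against 0.5, 0.49 and 0.5 in the simulations, with covariances of 0.84, 0.39 and 0.56 against 0.16. Part of each excess may come from the shared controls. With the WT libraries split, 1 for each knockout of a pair, an alternative chosen after the data were seen, the Smad2 and double knockouts shared 1570 or 1890 calls by the way round (994 or 347 opposite, covariance 0.47 or 0.86), the Smad2 and Smad3 knockouts 19 or 793 (9 or 172, 0.08 or 0.36) and the Smad3 and double knockouts 641 or 29 (212 or 1, 0.29 or 0.41). The shared counts moved with single libraries from 1109 (without double knockout replicate 1) to 3617 (without WT day 4 replicate 2), from 1 (without Smad3 knockout replicate 1) to 1981 and from 2 to 1961.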

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

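Of the tests reported here, those of the interaction were planned, and the window test and the length and GC test of chromosome 18 were set before their values were seen. The rule that overrode the window test, the tests of the induced genes, the break at Smad2, the positional reading and both streak tests were chosen after the result was seen.

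By the edgeR test of the interaction, the effect of Smad2 loss differed between WT cells and cells labelled Smad3 knockout for 3673 genes. Each knockout carried 1 line number, so these differences cannot be separated from traits of the lines. The values followed transcript length (Spearman 0.6), and with the length and GC offset 2221 of these calls were kept and 87 changed sign. The effect was -0.81 in WT and 0.38 in the Smad3 knockout for Smad4 (difference 1.19, adjusted p = 0.0128; a gene of the shifted part of chromosome 18, whose median interaction was 0.68, so the value is not clear of that shift), -4.68 and -1.55 for Foxa2 (3.13, 0.0419), -2.49 and -0.03 for Sox17 (2.46, 0.0351), 0.63 and -8.98 for Mesp1 (-9.61, 0.0255), -1.77 and -4.33 for Lefty1 (-2.56, 0.0475), 0.36 and -1.61 for Pou5f1 (-1.96, 0.0166) and -2.28 and 4.68 for Pappa2 (6.96, 0.0059), whose WT and Smad2 knockout levels rest on 16 and 3 counts. Without single libraries the count ran from 397 (Smad3 knockout replicate 2) to 7003 (WT day 4 replicate 2). Each of these calls except that of Pappa2 was lost without at least 1 Smad3 or double knockout library. Foxa2 had 1186 and 1701 counts in the WT day 4 libraries and 212 and 254 in the Smad3 knockout. It had 83 and 22 in the Smad2 knockout and 132 and 43 in the double knockout. For Sox17 these counts were 281 and 555, 141 and 209, 91 and 51, and 205 and 166 in that order. Mesp1 had 238 and 4 counts in the Smad2 knockout libraries and 1 and 0 in the double knockout. Its effect in WT was -4.53 without Smad2 knockout replicate 1.

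Of the fixed lists, 4 had an interaction by camera: primitive streak (median -2.86, adjusted p = 0.0359), mesoderm (-2.22, 0.00196), extraembryonic endoderm (2.09, 3.46e-05) and fibroblast and stroma (-1.43, 0.0116). With an estimated correlation the camera adjusted p was 0.655, 0.655, 0.655 and 0.606. By fry it was 0.295, 0.125, 0.00918 and 0.00473, so the streak and mesoderm calls did not hold there. The streak call was lost with the replicate block (adjusted p = 0.0505), with the length and GC offset (0.132) and without any 1 of 4 libraries (up to 0.459, Smad2 knockout replicate 1), and the fibroblast call without WT day 4 replicate 2 (0.0538).

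Genes induced in WT differentiation were lower in the Smad2 than in the Smad3 knockout (median -0.99). A transcript length and GC trend of the libraries could produce such a shift, but with the offset the median was -0.86. The set was chosen anew in that fit, with 3769 genes in place of 4293. The repressed set had 0.65 over 2167 genes there, in place of 0.95 over 3419. Undifferentiated cells carried along, as the only cause, would move naive genes and all repressed genes by like shares. The ratio of their median shares was 0.4 (16.7% of the way back to day 0 for 18 naive genes, 41.5% for repressed genes). The quartiles were 9.4 and 21.4% for naive and 17.6 and 68.4% for repressed genes. Such cells as part of the cause were not excluded, since naive genes did lie some of the way back. The length trend may also move the repressed share. An earlier stage, another composition of the embryoid bodies, and the line itself also stay open, since both libraries share 1 line number.

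Chromosome 18 genes were higher in the double than in the Smad3 knockout up to Smad2 and lower beyond it. A gain of the chromosome had been predicted, before the windows were seen, to put at least 80% of 10 Mb windows above 0.2, and 80% were, which met that prediction. The gain was set aside as the whole cause by a rule added after the windows were seen, because window 9 (19 genes) had a median of -0.84. The 32 genes beyond Smad2 had a median of -0.89 with 29 below 0. The length and GC trend does not account for the shift, as the chromosome's median was 0.48 with the offset. A candidate explanation is a copy number change with a break at the targeted gene: the best split against the Smad3 knockout fell next to Smad2, with a step of 1.43 against 0.65 for the next autosome. Against WT it fell 2 tested genes beyond Smad2 (1.55 against 0.67) and against the Smad2 knockout 12 beyond it (1.54 against 0.99, and 1.44 at Smad2 itself), a distance that 31.5% of 1000 simulated breaks at Smad2 reached. The place of the break therefore stays open, and that hypothesis was found and tested on the same data. A positional effect of losing both genes cannot be told apart from the line, since both libraries share it; the step in the Smad2 knockout was 0.1.

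Streak genes were higher in Smad2 knockout replicate 1 than in replicate 2 (median log2 ratio 3.52, 15 of 16 above 2-fold). Other lists differed too: 10 of 15 WNT response and 8 of 16 BMP response genes were above 2-fold and 0 below. Of 22 mesoderm genes 12 were above and 1 below, and of 20 naive genes 1 was above and 8 below. Admixed WT cells at the share that T implies (69.8% of the higher WT library) would bring at least 31.6 CPM of the 5 Y-linked list genes, a minimum taken at the lowest Y-linked level of the WT and Smad3 knockout libraries, and 0 were found. Smad3 knockout cells could not bring T to 74.3 CPM, as it stood at 56.9 and 64.6 there. That test was first run on all 12 annotated Y genes, where 106 of the 130 CPM needed were found and nothing was decided; 105 of these came from Gm47283, which stood at 165 CPM in replicate 2 as well, and the fixed list was used after that was seen. A difference between submissions might raise the same genes elsewhere, but the medians were -0.88 in WT and -0.3 in the Smad3 knockout. A difference between the cultures in stage or streak formation stays open and was not tested.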

How the results depend on the processing

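The length and GC offset, leaving out chromosomes 18 and Y, list counts without single doubted libraries, pairing WT day 4 with the Smad3 knockout and splitting the WT libraries were chosen after the data were seen; the other alternatives were planned. For the 225 named gene values, 4542 alternative values kept direction and side of the threshold, 320 lost the call, 120 gained it and 55 turned sign. Over the whole panel, 31 of 160 values turned sign under at least 1 alternative, 1 of them among 86 called. Unless stated, the cause was not tested.

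Counts of called genes outside 1.5 times the main count were, for the Smad2 knockout against WT, 2461 (compared groups alone) and 4598 (absolute log2 fold change of at least 1). For the Smad3 knockout they were 191 (library totals), 1096 (no filter), 278 (submission block), 1505 (offset), 512 (paired), 791 (DESeq2), 54 (TPM + 0.1) and 0 (compared groups alone, edgeR, where fewer libraries estimate the spread, though the count for the double against the Smad3 knockout rose there, and 2421 genes had an unadjusted p under 0.05). For the double knockout against WT they were 6923 (offset), 2778 (compared groups) and 2743 (TPM + 0.1), for the Smad2 against the Smad3 knockout 4232 (fold threshold), for the double against the Smad3 knockout 5286 (offset), 6498 (compared groups) and 1694 (TPM + 0.1), and for the interaction 5512 (TPM + 1). With an estimated correlation 0 of 97 list calls by camera held, and the induced and repressed sets had 0.76 and -0.82 (double against Smad2 knockout) and -0.17 and 0.07 (double against Smad3 knockout) with adjusted p = 0.0881, 0.123, 0.415 and 0.529. DESeq2 shared calls were 397 (Smad2 and Smad3 knockouts) and 536 (Smad3 and double knockouts), and with the WT libraries split 19 or 793 and 641 or 29.

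Splits into higher and lower moved by over 10 points with library totals (WT day 4 against day 0 6887 and 3306, Smad2 knockout 2126 and 4808, Smad3 knockout 173 and 18, Smad2 against Smad3 knockout 1571 and 5369, double against Smad2 knockout 5479 and 2266, interaction 2763 and 1125) and with TPM + 1 (7098 and 1487, 800 and 6168, 97 and 6, 507 and 6377, 7082 and 673, 5089 and 423 in that order, and 2046 and 1021 for the double knockout against WT and 1218 and 836 against the Smad3 knockout). The Smad3 knockout split was 686 and 410 with no filter, 643 and 862 with the offset, 322 and 190 when paired and 506 and 285 by DESeq2. The median of all genes was 0.097, 0.377 and 0.632 for WT day 4 against day 0 with TMM, library totals and TPM + 1, and -0.012, -0.199 and -0.507 for the Smad2 knockout.

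Leaving out 1 library in turn gave 6504 to 10979 calls for WT day 4 against day 0, 4571 to 8864, 3 to 2709 and 2126 to 6051 for the Smad2, Smad3 and double knockouts against WT, 1898 to 8569 for the Smad2 against the Smad3 knockout, 3693 to 9485 and 1028 to 4409 for the double against the Smad2 and Smad3 knockouts, 397 to 7003 for the interaction, 88 to 112 list calls, a repressed-set median of 0.01 to 0.18 (double against Smad3 knockout), and 1 to 1981, 1109 to 3617 and 2 to 1961 shared calls (Smad2 with Smad3, Smad2 with double, Smad3 with double).

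With the replicate block 10357, 7206, 99, 4571, 6774, 7872, 3036 and 3775 genes were called in the 8 comparisons in the order of the preceding ranges, and 94 lists. Same-numbered libraries deviated together with a correlation of 0.86 for WT day 4 and the Smad3 knockout and -0.28 to 0.39 for the other pairs of groups, so pairing by number was tried for that pair of groups alone, where the number and the submission coincide.

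Values turned sign as follows. For WT day 4 against day 0, Smad2 was -0.09 with the offset, Nodal 0.22 with the offset and 0.25 with TPM + 1 and TPM + 0.1, Lefty2 0.24 and 0.25 with these, Rhox5 0.52 with the offset and 0.08 on both TPM scales, and Smad7 0.46 and 0.49 on these. For the Smad2 knockout against WT, Mesp1 was -0.8 with the offset and -0.43 and -1.41 on the TPM scales, Pou5f1 -0.7 with the offset and -0.32 on both TPM scales, and Rhox5 -0.1 with the offset. For the Smad3 knockout against WT, Smad2 was 0.02 on both TPM scales. For the Smad2 against the Smad3 knockout, Nodal was -0.01 with library totals, -0.23 with the offset and -0.54 and -0.57 on the TPM scales. For the double against the Smad2 knockout, Smad2 was -0.69 with the offset, Smad3 0.09 with library totals and 0.61 and 0.69 on the TPM scales, Cer1 0.19 with library totals, 0.34 with the offset and 0.01 and 0.13 on the TPM scales, and Nanog 0.35 on both TPM scales. For the interaction, Smad2 was -0.6 with the offset, Smad3 0.18 and 0.24 on the TPM scales, Foxh1 0.51 with the offset, Eomes 0.27 and 0.17 on the TPM scales, Gsc 0.3 with the offset and 0.32 with TPM + 1, and Nodal 0 with TPM + 1.

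Over the left-out libraries, values that turned sign ran from -4.53 to 1.62 for Mesp1 and 0 to 0.96 for Pou5f1 (Smad2 knockout against WT), from -0.36 to 0.05 for Smad2 and -0.07 to 0.11 for Smad4 (Smad3 knockout against WT), from -6.26 to 0.29 for T, -0.28 to 0.72 for Nodal and -0.41 to 0.23 for Lefty2 (Smad2 against Smad3 knockout), from -0.88 to 3.04 for Cer1 (double against Smad2 knockout), and from -1.82 to 0.36 for Eomes and -7.39 to 0.62 for Mixl1 (interaction). Depth limits the genes with few counts, such as Cer1 in the Smad2 and double knockouts.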

Other observations

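The gene groups and the comparison in this part were chosen after the result was seen.

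Placental genes were higher in the double knockout than in the single ones. Of 20 such genes 16 passed the filter (prolactins, cathepsins, serpins and 4 others, in families with near copies, so that single members are uncertain). Several, such as Prl3d1 and Ceacam15, had no count in WT or the Smad3 knockout and passed through the double knockout. The share called there was therefore partly set by the filter. By edgeR all 16 were called higher in the double knockout than in WT, 10 in the Smad2 knockout and 1 in the Smad3 knockout. Set directly against the Smad2 and Smad3 knockouts, 13 and 15 were higher in the double knockout, and the interaction was called for 2 with a positive and 1 with a negative value. The Xlr genes, an X-linked family of near copies, were called higher in the double knockout (9 of 9) and the Smad3 knockout (6 of 9) and lower in the Smad2 knockout (3 of 9). Between the single knockouts 9 of 9 Xlr genes were lower in the Smad2 knockout. Antigen presentation genes were called lower in the double knockout (13 of 19, median log2 fold change -1.59), with 5 higher and 1 lower in the Smad2 knockout and 0 called in the Smad3 knockout; the interaction was called negative for 14. Of 20 interferon response genes 9 were lower and 4 higher in the double knockout.

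Smad2 knockout embryoid bodies at day 4 differed from WT at day 0 as well. Against WT at day 0, edgeR called 2458 genes higher and 1805 lower, 4263 in all. Of the naive pluripotency genes 18 of 20 were lower, 13 of 22 extraembryonic endoderm genes were higher and 1 lower, and 8 of 14 trophoblast genes were higher.

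Fold changes followed transcript length in the comparisons that involve day 0 or the Smad2 knockout. Across 11212 genes, which are not independent, the Spearman correlation was 0.57 for WT day 4 against day 0, -0.63 for the Smad2 knockout and -0.05 and 0.06 for the Smad3 and double knockouts against WT, -0.65 for the Smad2 against the Smad3 knockout, 0.62 and 0.1 for the double against the Smad2 and Smad3 knockouts, and 0.6 for the interaction.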
